A study of Bos taurus with 8 samples.

How the data were processed

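Libraries had been made from total RNA with a stranded, poly(A)-selecting kit, per the labels' protocols. The series comprises 8 samples of BUTE cells, 4 with DMSO and 4 with progesterone. The deposited table was read as estimated counts per gene for 8 columns. Each column total lies within 0.1 of a whole number and totals differ between columns. The table's name gives length normalization, which these totals neither show nor exclude. The submitters' processing notes name bcl2fastq, Salmon 1.4.0 and the bovine build ARS-UCD1.2, with no role or order. How transcripts were summed to genes is not given in the sources used here. Because estimated counts assign reads shared between near-identical copies by a model, genes of multigene families (histones, ribosomal proteins and their pseudogenes, HSPA1 copies) are uncertain.

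The table lists 28709 genes by Entrez Gene identifier and symbol, and 8766 had a rounded count of 0 in every library. In the reference gene table (assembly ARS-UCD2.0) 26025 of the identifiers were found; it served for synonyms of gene symbols and, in 1 check, for gene lengths, and no coordinates are printed. Chromosomes are those of the deposited table. Column names give the group of each library but not which sample it is, so each library entered its group as a replicate without a number. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 14.9 and 139, so none was treated as a repeat of another.

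The deposited estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the group (13557 genes), scaled by TMM factors and tested with edgeR's quasi-likelihood test (version 4.0.16, robust estimation, two-sided) between progesterone and DMSO, with all 8 libraries and the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are TMM-scaled. The standard error of a log2 fold change is its size divided by the square root of the test's F, and 95% intervals use the t distribution with the fit's degrees of freedom. R was version 4.3.3.

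The 48 gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. Measured members of a list are those kept by the filter, and members below it were not tested. Lists with at least 4 measured members (46) were tested with camera of limma 3.58.1 (two-sided) at a preset correlation of 0.01 on log2 CPM from voom, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were computed beside it. No member of the list of mitochondrially encoded proteins was matched, and the core enzyme H6PD was not matched by symbol or synonym; both are not analysed here. For each list the count of members past the threshold is given over all genes and adjusted over the list alone. The deviation of a list in a library is the median over its genes of the log2 CPM (prior count 2) minus the mean of the 8 libraries.

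Genes are named by these parts of the rule: the 8 with the highest and the 8 with the lowest log2 fold change among genes that pass, have a mean of at least 1 CPM in a group, do not overlap between groups and have a symbol that is not a placeholder; the 10 with the smallest p under the same conditions; every measured core enzyme of the pentose phosphate pathway and every steroid receptor; up to 8 members with the smallest p of the glucose uptake, glycolysis and glycogen lists and up to 4 of every other list. Not every gene the rule allows is described, and some members counted in their lists are not reported here.

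Alternatives were DESeq2's size factors, library size only, upper-quartile factors, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma voom, unrounded counts, no robust estimation, a threshold of 0.01 and leaving out each library in turn. Leaving out DMSO R7 and R9 together, a model term for these 2 libraries and the column number as a block were added after the data were seen. Counts were simulated with the real genes' means and library sizes, and 200 of 13557 genes changed. Spreads for 8 libraries were those within 3 sets: DMSO R1 and R3, DMSO R7 and R9, and progesterone. The distance of R7 and R9 from the other DMSO libraries was left out, so the rates do not describe the real 8 libraries. On these counts the test recovered 68.0% of 1.5-fold and 76.0% of 2-fold changes, with 11 false calls. Simulating 2 DMSO and 4 progesterone libraries with 200 of 13764 genes changed, it recovered 52.0% and 85.0%, with 15 false calls. In both, a list of genes raised together was called and 0 of 40 unchanged lists were. Members of these lists were simulated independently of each other, so the check does not cover lists whose genes vary together. In the real data the estimated correlation of the ribosomal list was 0.593.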

Results

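Poly(A) RNA was sequenced from BUTE cells, an immortalized epithelial line made from the uterus of a Holstein cow. Cells were held for 24 h without serum and steroids but with insulin-like growth factor 1, and then received either the vehicle DMSO or 10 µM progesterone for 24 h, with the growth factor at 50 ng/ml. Each group had 4 libraries. The libraries held between 23810861 and 32509786 estimated counts, and between 16545 and 17625 genes had a count in a library. Library totals overlapped between the groups. The labels do not say whether the 4 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries. Libraries are named after the columns of the deposited table (DMSO R1, R3, R7 and R9, progesterone R1, R2, R3 and R6), whose numbers could not be matched to the replicate numbers of the samples.

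The first principal component of log2 CPM held 66.8% of the variance and separated DMSO R7 and R9 from the other 6 libraries. Across genes, the correlation of R7 with R9 was 0.992. Their correlation with the other 6 libraries was between 0.936 and 0.954, while the other 6 correlated with each other at 0.981 to 0.993. In R7, 221 of 12538 genes lay over 4-fold from the median of the 8 libraries, and in R9 223, against 3 to 10 in each of the others. Each comparison is therefore given with all 8 libraries, as planned, and again without these 2, a comparison of 2 DMSO with 4 progesterone libraries that was chosen after the structure was seen.

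**Figure D1:**
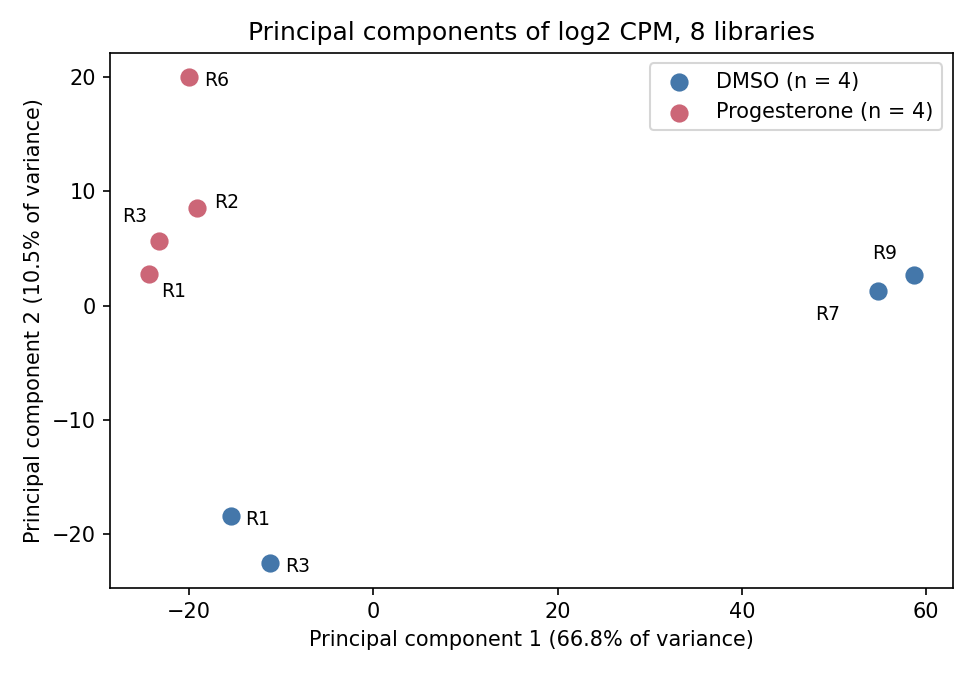
Principal components 1 and 2 of log2 CPM, each axis with its percentage of variance, with 1 point per library coloured by group. DMSO R7 and R9 lie alone at the right on component 1, which holds 66.8% of the variance, and the remaining DMSO libraries part from the progesterone libraries on component 2, which holds 10.5%.

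The first comparison asked which genes differed after 24 h of progesterone. Of 13557 genes tested, 359 passed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), 229 higher and 130 lower with progesterone. Of these, 91 changed at least 2-fold, 63 higher and 28 lower. Without DMSO R7 and R9, 162 of 13764 genes passed, 137 higher and 25 lower. The comparisons shared 122 genes, 104 higher and 18 lower, and 6 of their libraries. The 359 genes called with all libraries had the same sign of change in both. All 359 were without overlap between the groups, so leaving out libraries could hardly turn a sign. The match of signs is therefore no separate evidence. With a model term for R7 and R9 the count was 278. Leaving out 1 library at a time gave between 42 and 1782 genes: 1782 without DMSO R1, 795 without DMSO R3, 51 without DMSO R7, 82 without DMSO R9, and 42, 48, 76 and 53 without progesterone R1, R2, R3 and R6. The groups did not overlap at 2193 genes, 16.2% of those tested. Chance gives 2.86% if every library is equally likely to take any rank. DMSO R7 and R9 stand apart together in the same group, so 2.86% may be too low a baseline. The excess over chance was therefore not measured.

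The gene with the smallest p was TSC22D3 (Entrez Gene 100125309, chromosome X), which encodes the glucocorticoid-induced leucine zipper. It rose from 30.3 ± 0.368 CPM with DMSO to 67.2 ± 6.83 CPM with progesterone (mean ± SD, n = 4 each). This was 2.22-fold (log2 fold change 1.15 ± 0.09 SE, edgeR adjusted p = 0.00159). XDH (280960, chromosome 11), the xanthine oxidoreductase of purine breakdown, rose 3.64-fold from 50.5 ± 10.6 to 184 ± 24.3 CPM. The tumour suppressor MTUS1 rose 2.22-fold, the decoy receptor TNFRSF10D 1.63-fold, the galactosyltransferase B4GALT5 1.99-fold and the hypoxia-inducible factor EPAS1 by 1.07 on the log2 scale. LPIN1, a phosphatidate phosphatase of triglyceride synthesis, rose 2.37-fold, ATRAID 1.58-fold and the tissue plasminogen activator PLAT 2.46-fold. CRY1 (535947, chromosome 5), a repressor of the circadian clock, fell from 15.1 ± 1.61 to 6.82 ± 0.375 CPM, 2.22-fold lower. These 10 genes had edgeR adjusted p between 0.00159 and 0.00784, and each also passed without R7 and R9, with adjusted p between 0.000498 and 0.0143.

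Among genes with the largest increases, P4HA3 (414348, chromosome 15), a subunit of collagen prolyl hydroxylase, rose 11.5-fold from 1.95 ± 0.959 to 22.4 ± 9.54 CPM. The chemokine scavenger ACKR4 rose 9.08-fold, AGR2, a secretory-pathway disulfide isomerase, 8.64-fold, and SLC27A2, a fatty acid transporter and acyl-CoA synthetase, 7.37-fold, from DMSO means of 0.663, 0.278 and 0.197 CPM. Without R7 and R9 the log2 fold change of P4HA3 moved from 3.53 to 4.25, that of ACKR4 from 3.18 to 2.59 and that of AGR2 from 3.11 to 4.47, the last against DMSO values of 0.171 and 0.0367 CPM. ABCA1 (535379, chromosome 8), the cholesterol exporter, rose 7.32-fold from 34.7 ± 17.2 to 254 ± 9.02 CPM, and complement factor CFB rose 5.51-fold. RSPO1 rose 7.13-fold and ALDH8A1 5.35-fold from under 1 CPM, and neither passed without R7 and R9 (edgeR adjusted p = 0.168 and 0.0960), with log2 fold changes from 2.83 to 2.34 and from 2.42 to 2.18.

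Of the 8 genes with the largest decreases, 6 did not pass without R7 and R9. KRT6A, a keratin, was 10.2-fold lower with progesterone (log2 fold change -3.35 ± 0.62 SE), and DKK2, an inhibitor of WNT signalling, 9.06-fold lower (-3.18 ± 0.64). Their log2 fold changes without R7 and R9 were -2.02 and -1.62, and both still passed (edgeR adjusted p = 0.0366 and 0.00888). TXNIP, a glucose-responsive arrestin that restrains glucose uptake, fell from 89.6 ± 11.8 to 26.1 ± 13.8 CPM, 3.43-fold lower, with an adjusted p of 0.0303. TNN, COL17A1, GTSF1, DGKI and PDZRN4 were between 3.32-fold and 5.43-fold lower. TXNIP and these 5 did not pass without R7 and R9, with edgeR adjusted p between 0.0672 (DGKI) and 0.146 (TXNIP). Their log2 fold changes, with all libraries and then without these 2, were -2.17 and -1.40 for GTSF1, -2.41 and -1.50 for COL17A1, -2.44 and -1.96 for TNN, -1.78 and -1.63 for TXNIP, -1.96 and -2.14 for DGKI and -1.73 and -1.86 for PDZRN4, so the last 2 lost the call without a smaller change.

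**Figure D2:**
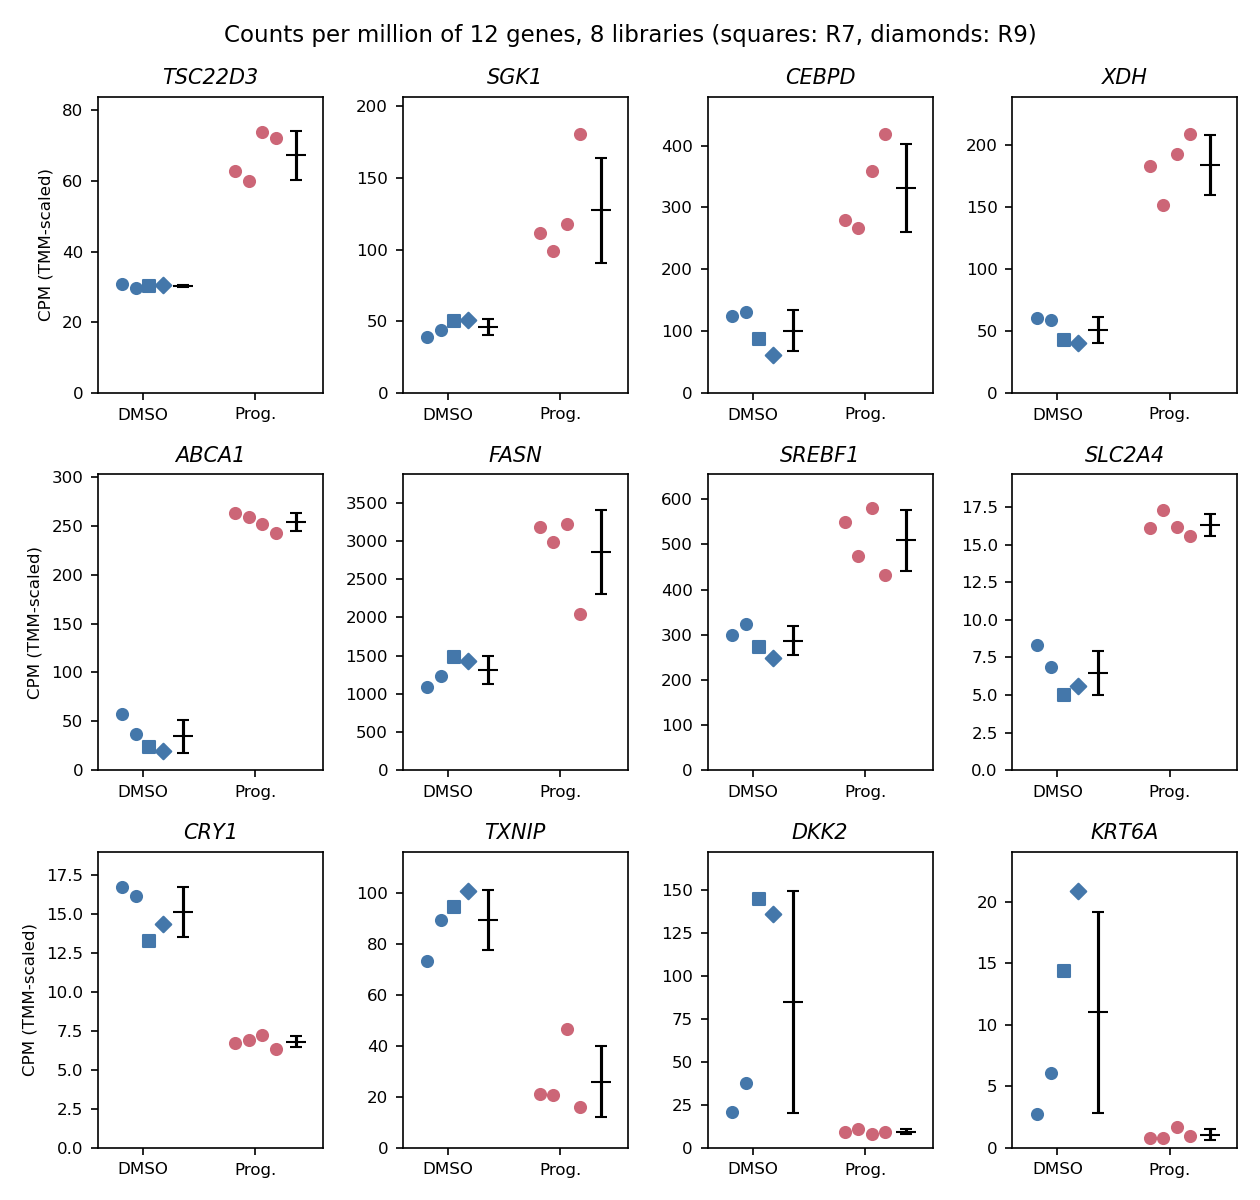
CPM values, scaled by TMM factors, of 12 genes in each library, with DMSO in blue and progesterone in red; bars are the mean ± SD (n = 4), squares mark DMSO R7 and diamonds DMSO R9. TSC22D3 lies near 30.3 CPM in the 4 DMSO libraries, R7 and R9 included, while DKK2 and KRT6A are highest in R7 and R9.

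The title of the series names the pentose phosphate pathway, which makes NADPH and ribose 5-phosphate from glucose 6-phosphate. Of 7 core enzymes measured, none passed in edgeR when adjusted over all genes, and 4 had an unadjusted p under 0.05. DESeq2 called 2 of the 7 and limma voom 0. Adjusted over the list alone, 2 passed, RPE among them. The pathway was named by the study of these samples, so the count over the list is not independent evidence. RPE (533764, chromosome 2), the epimerase of the non-oxidative branch, was at 33.8 ± 3.88 CPM with DMSO and 26.4 ± 1.77 CPM with progesterone (-0.36 ± 0.11 SE), with an edgeR adjusted p of 0.0231 over the list and 0.0817 over all genes. Without R7 and R9 none passed over the list, with an adjusted p of 0.116 for RPE.

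The other core enzymes reported here did not pass in either adjustment. The log2 fold change was 0.26 ± 0.10 for transketolase TKT (SE, adjusted p = 0.0586 over the list) and 0.28 ± 0.12 for PGD, the enzyme that makes ribulose 5-phosphate (0.0634, edgeR as above). It was 0.14 ± 0.10 for transaldolase TALDO1, 0.20 ± 0.16 for PGLS and -0.08 ± 0.12 for RPIA. The value for PGLS was -0.07 without R7 and R9, since both libraries were low for this gene. TKT did not overlap between the groups, at 517 ± 38.5 CPM with DMSO and 619 ± 61.8 with progesterone. As a list the 7 genes had a median log2 fold change of 0.20 and a camera adjusted p of 0.351 (0.849 with an estimated correlation). Fry gave the list an adjusted p of 0.283 for a shared direction and 0.0141 for changes in either direction. The latter was also low for lists that camera did not call, such as hexose transporters (0.00219) and glycogen genes (0.0177). It is therefore not particular to this pathway. Among 9 enzymes that feed or drain ribose phosphate, PRPS2, a phosphoribosyl pyrophosphate synthetase, fell 1.31-fold (log2 fold change -0.40, edgeR adjusted p = 0.0498, and -0.42 and 0.0865 without R7 and R9) and 8 did not pass. Adjusted over the list alone PGM2, which interconverts sugar phosphates, also fell (log2 fold change -0.50 ± 0.15 SE), and without R7 and R9 it did not pass over the list (-0.23, adjusted p = 0.211).

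**Figure D3:**
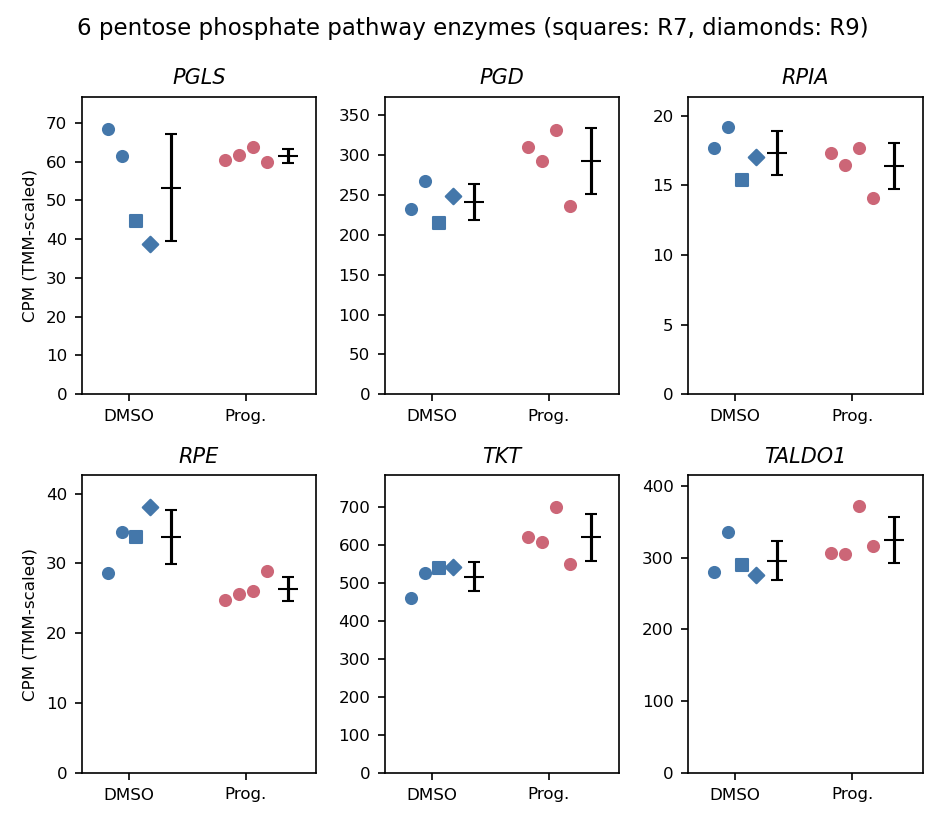
CPM values, scaled by TMM factors, of 6 core enzymes of the pentose phosphate pathway in each library, with DMSO in blue and progesterone in red; bars are the mean ± SD (n = 4), squares mark DMSO R7 and diamonds DMSO R9. TKT does not overlap between the groups, and PGLS is lower in R7 and R9 than in the other 6 libraries.

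Of 10 hexose transporters, 1 rose and 9 did not pass, over all genes and adjusted over the list alone. SLC2A4 (282359, chromosome 19), the insulin-responsive glucose transporter GLUT4, rose 2.52-fold from 6.46 ± 1.46 to 16.3 ± 0.714 CPM (log2 fold change 1.33 ± 0.16 SE, edgeR adjusted p = 0.00784) and 1.11 on the log2 scale without R7 and R9 (0.00584). SLC2A1, the basal transporter, was at 103 ± 26.9 CPM with DMSO and 80.8 ± 36.7 CPM with progesterone, within the spread of the libraries (edgeR adjusted p = 0.490). SLC2A3 had a log2 fold change of -1.24 ± 0.60 with all libraries and 0.14 ± 0.47 without R7 and R9 and did not pass in either. Of 27 glycolytic and lactate-handling genes, ENO3, an enolase, fell 1.49-fold (log2 fold change -0.57, edgeR adjusted p = 0.0470, and -0.50 and 0.138 without R7 and R9) and 26 did not pass, with the same count adjusted over the list alone. The lactate carrier SLC16A1 and the mutase PGAM1 had log2 fold changes of -0.53 ± 0.14 and -0.31 ± 0.14, and of -0.27 and -0.37 without R7 and R9. Of 23 glycogen genes, GAA, the lysosomal glucosidase that degrades glycogen, rose by 0.49 on the log2 scale (edgeR adjusted p = 0.0325, and 0.38 and 0.0681 without R7 and R9) and 22 did not pass. Adjusted over the list alone, 2 others fell, GSK3B among them (-0.53 ± 0.15 SE), and neither did without R7 and R9, where GSK3B was at -0.19. Glycogen synthase GYS1 had a log2 fold change of 0.36 ± 0.13 and did not pass. Camera adjusted p was 0.855 for the transporters, 0.609 for glycolysis and 0.855 for glycogen.

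Of 25 genes of fatty acid and triglyceride synthesis, 8 rose, 0 fell and 17 did not pass, and adjusted over the list alone 12 rose and 2 fell. FASN, the fatty acid synthase, rose 2.18-fold from 1310.0 ± 181 to 2855 ± 550.5 CPM (log2 fold change 1.12 ± 0.16 SE, edgeR adjusted p = 0.0128). SREBF1, the transcription factor that drives these genes, rose 1.77-fold and ACSL4, an acyl-CoA synthetase, 1.64-fold. Of 23 genes of cholesterol synthesis and uptake, 7 rose and 16 did not pass, and 11 rose adjusted over the list alone. The examples with the smallest p were HSD17B7, 1.94-fold, MSMO1, 1.46-fold, MVK, 1.48-fold, and IDI1, 1.45-fold. Of 10 genes of sterol export and liver X receptor response, 3 rose and 7 did not pass, and 5 rose adjusted over the list alone. Beside ABCA1 these were MYLIP, a ligase that degrades the LDL receptor, at 1.94-fold, and LPCAT3, a phospholipid remodelling enzyme, at 1.41-fold. Median log2 fold changes were 0.30, 0.37 and 0.25 for the 3 lists, and 0.38, 0.42 and 0.46 without R7 and R9. Progesterone R6 had median deviations of -0.05 for the fatty acid list and -0.06 for the cholesterol list, against 0.23 to 0.28 in the other 3 progesterone libraries and a highest DMSO value of -0.06 (R7) and -0.12 (R9). Camera adjusted p was 0.000197, 2.56e-08 and 0.00144, and adjusted p = 0.630, 0.557 and 0.385 with an estimated correlation. Without R7 and R9, 9, 4 and 3 genes rose over all genes and 16, 19 and 5 adjusted over each list alone, and none fell; MVK and IDI1 were among those that no longer passed (edgeR adjusted p = 0.0646 and 0.0610), with log2 fold changes of 0.57 with and without these libraries for MVK and of 0.54 and 0.46 for IDI1.

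Of 17 measured genes commonly induced by progestins or glucocorticoids through their shared response element, 8 rose and 9 did not pass, and adjusted over the list alone 10 rose and 1 fell. SGK1, a serum- and glucocorticoid-regulated kinase, rose 2.77-fold from 46.0 ± 5.56 to 127 ± 36.5 CPM (log2 fold change 1.47 ± 0.18 SE, edgeR adjusted p = 0.00784). The transcription factor CEBPD rose 3.29-fold and the clock gene PER1 1.74-fold. The list had a median log2 fold change of 0.50 and a camera adjusted p of 0.000310 (adjusted p = 0.512 with an estimated correlation). The comparison without R7 and R9 tested 20 genes of this list, 3 more than before; 7 rose, 12 adjusted over the list alone, and the median was 0.62.

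Of 15 steroid receptors listed, 9 were kept by the filter and tested. None of the 9 passed in edgeR, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was found for 1, and DESeq2 and voom called 0. The nuclear progesterone receptor PGR (100848466, chromosome 15) was at 10.3 ± 2.78 CPM with DMSO and 13.7 ± 3.58 CPM with progesterone (log2 fold change 0.42 ± 0.23 SE, edgeR adjusted p = 0.268), and its log2 fold change was 0.14 ± 0.21 without R7 and R9. The glucocorticoid receptor NR3C1 was at 56.6 ± 10.1 and 65.6 ± 9.40 CPM and the oestrogen receptor ESR1 at 28.3 ± 12.1 and 37.6 ± 8.49 CPM. Among membrane receptors, PGRMC2 was at 88.3 and 82.6 CPM, PGRMC1 at 55.3 and 44.0, PAQR8 at 18.9 and 22.8, PAQR6 at 4.87 and 5.02 and PAQR7 at 1.73 and 1.95. The log2 fold change moved, without R7 and R9, from 0.41 to -0.01 for ESR1, from 0.28 to -0.01 for PAQR8 and from -0.33 to -0.11 for PGRMC1. Of 24 genes reported to follow progesterone in endometrial epithelium, none passed over all genes in edgeR (9 had an unadjusted p under 0.05, DESeq2 called 5 and voom 0). Adjusted over the list alone 1 fell, the cell-surface mucin MUC1 (log2 fold change -1.25 ± 0.30 SE); without R7 and R9 it was at -0.72 and did not pass (adjusted p = 0.147 over the list). SPP1, which encodes osteopontin, was at 1230.0 ± 664 CPM with DMSO and 494 ± 88.8 CPM with progesterone and did not pass (edgeR adjusted p = 0.0896), with a log2 fold change of -1.31 and, without R7 and R9, -0.43. The median deviation of this list was 0.27 and 0.51 (log2) in R7 and R9 and between -0.25 and -0.02 in the other 6 libraries. Camera adjusted p was 0.683 for the receptors and 0.755 for the endometrial genes.

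With all libraries, 13 of 46 lists passed camera's test, 8 higher and 5 lower. None passed with an estimated correlation, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.385. Sterol export and nucleotide synthesis were lost there although their estimated correlations, -0.0857 and -0.00677, lay below the preset 0.01. Correlation between genes is thus not the only reason why lists were lost with that setting. Fry called 6, 5 of them among the 13. Beside the 4 lists above, ribosomal proteins were higher, with a median log2 fold change of 0.39. Of 71 members, RPL31 alone rose over all genes (1.49-fold, edgeR adjusted p = 0.0497), and 65 rose adjusted over the list alone; without R7 and R9 none did. Camera adjusted p was 5.14e-22, and adjusted p = 0.630 with an estimated correlation. Median deviations of this list were -0.14, -0.06, -0.31 and -0.25 in the DMSO libraries and -0.05, 0.20, 0.23 and 0.45 in the progesterone libraries. Respiratory chain subunits had a median of 0.23, with 0 of 55 past the threshold in either adjustment; 16 had an unadjusted p under 0.05, and DESeq2 called 9 and voom 0 (camera adjusted p = 0.00113, and adjusted p = 0.766 with an estimated correlation). Their deviation in progesterone R1 was -0.16, as in DMSO R1 and below the 0.01 of DMSO R3, against 0.10 to 0.26 in the other 3 progesterone libraries. Lysosomal and autophagy genes had a median of 0.17; SGSH, a heparan sulfate hydrolase, rose by 0.58 on the log2 scale, and 8 of 31 rose adjusted over the list alone, 0 without R7 and R9 (0.00174, and adjusted p = 0.699 with an estimated correlation), with a deviation of 0.05 in DMSO R3 and 0.04 to 0.25 with progesterone. Of 24 genes of insulin-like growth factor signalling, PIK3IP1, an inhibitor of phosphoinositide 3-kinase, rose 2.34-fold, FOXO3 1.62-fold, and TXNIP fell; adjusted over the list alone 4 rose and 1 fell, and 4 and 2 without R7 and R9 (camera adjusted p = 0.0154, and adjusted p = 0.699 with an estimated correlation). RPL31 and SGSH did not pass without R7 and R9 (edgeR adjusted p = 0.139 and 0.0818), with log2 fold changes from 0.57 to 0.41 and from 0.58 to 0.45.

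With all libraries 5 lists were lower with progesterone. Extracellular matrix and TGF-beta targets had a median log2 fold change of -0.60 with all libraries and -0.05 without R7 and R9, and the list's median deviation was 0.62 and 0.71 in these 2 libraries. Of 28 members, 3 fell, among them COL17A1 and the matricellular protein POSTN at 2.86-fold lower, and 9 fell adjusted over the list alone, 4 without R7 and R9. Camera adjusted p was 0.000378, and adjusted p = 0.742 with an estimated correlation. Of 25 chaperones and unfolded protein response genes, HYOU1 fell 1.74-fold and DNAJB11 1.67-fold, and 8 fell adjusted over the list alone, 2 without R7 and R9, with deviations of 0.19 and 0.15 in R7 and R9 (0.00151, and adjusted p = 0.712 with an estimated correlation). Of 17 heat shock genes, HSP90AA1 fell 1.37-fold, and 6 fell adjusted over the list alone, 3 without R7 and R9, with deviations of 0.18 and 0.25 (0.0149, and adjusted p = 0.630 with an estimated correlation). Of 29 interferon-stimulated genes, IFIH1 fell 1.77-fold and PARP9 1.82-fold, and adjusted over the list alone 7 fell and 2 rose, none of them without R7 and R9, with deviations of 0.43 and 0.41, and -0.11 in DMSO R3 against -0.27 to -0.01 with progesterone (0.0115, and adjusted p = 0.760 with an estimated correlation). Of 23 nucleotide synthesis genes, CTPS1, a CTP synthetase, fell 1.61-fold, and 4 fell adjusted over the list alone, 3 without R7 and R9, with deviations of -0.01 and 0.09 (0.0245, and adjusted p = 0.512 with an estimated correlation). Of the members named here, HYOU1 passed without R7 and R9 and the others did not, with edgeR adjusted p between 0.0538 (CTPS1) and 0.154 (PARP9). Log2 fold changes moved from -0.80 to -0.43 for HYOU1, from -0.74 to -0.41 for DNAJB11, from -1.52 to -0.88 for POSTN, from -0.69 to -0.41 for CTPS1, from -0.86 to -0.57 for PARP9, from -0.83 to -0.66 for IFIH1 and from -0.45 to -0.33 for HSP90AA1. Without R7 and R9, camera adjusted p was 0.0769 for heat shock genes and 0.297 for interferon-stimulated genes, and 11 of the 13 lists passed in the same direction, while no list passed there with an estimated correlation. The amino acid stress list, higher with a camera adjusted p of 0.000647, and the DNA replication list, lower with 0.00566, passed without R7 and R9 but not with all libraries (adjusted p = 0.650 and 0.649 with an estimated correlation).

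**Figure D4:**
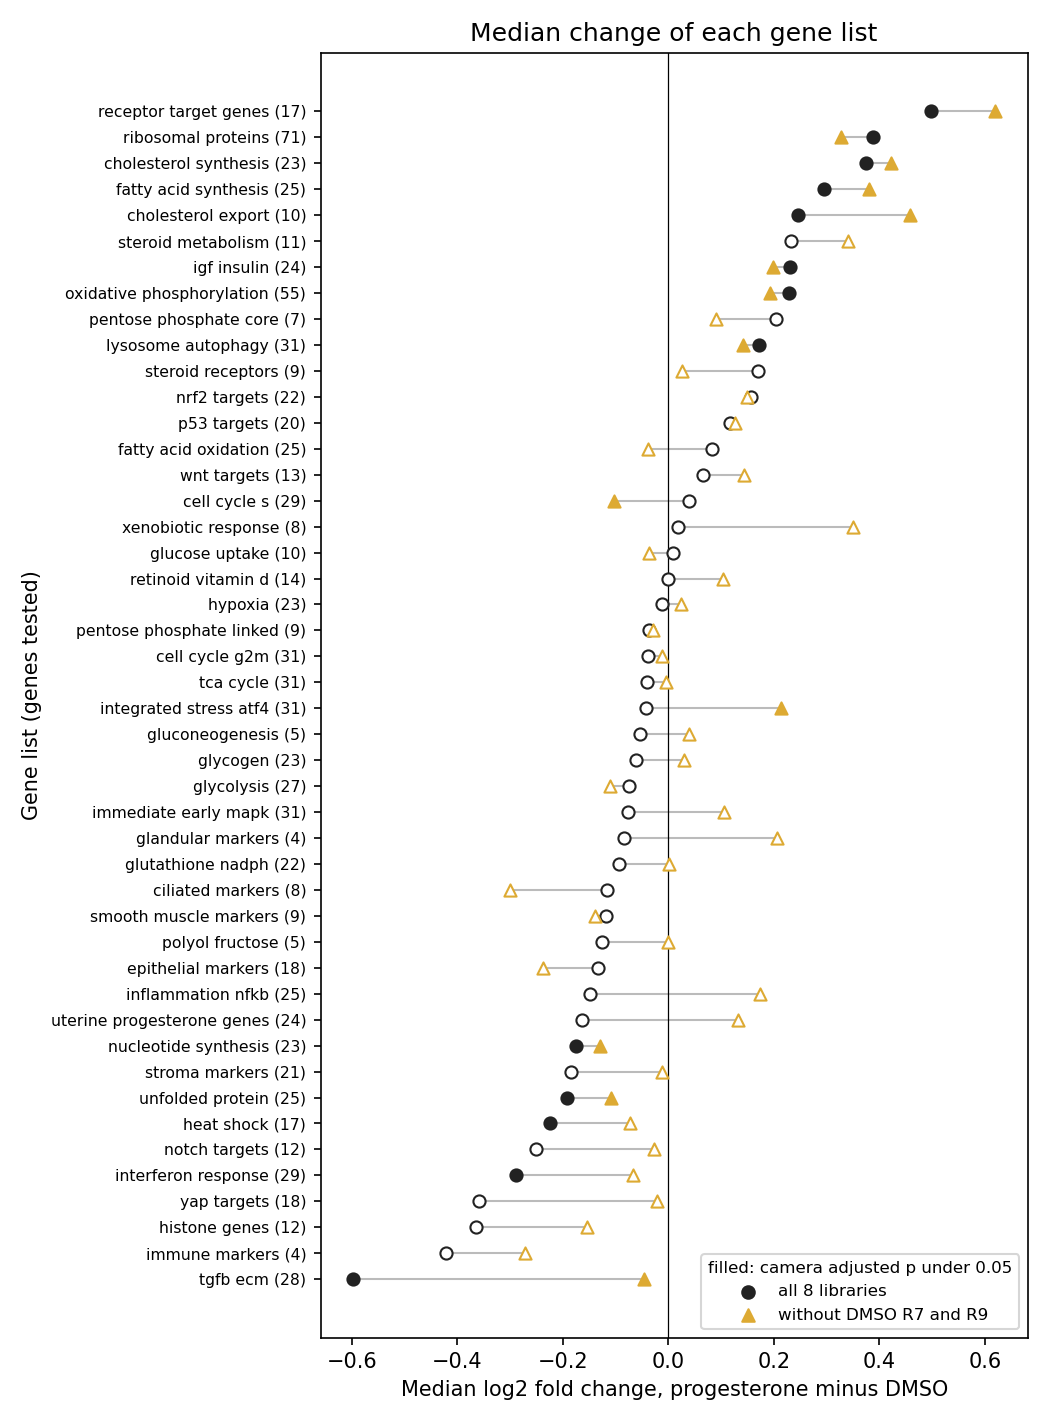
Median log2 fold change (progesterone minus DMSO) of each of 46 gene lists, with the number of genes tested in brackets, for all 8 libraries (black circles) and without DMSO R7 and R9 (yellow triangles); filled symbols mark a camera adjusted p under 0.05 with the preset correlation. The matrix and TGF-beta list moves from -0.60 to -0.05, while the lipid synthesis and receptor target lists lie above 0 in both.

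Other lists gave single genes. Of 31 genes of pyruvate entry and the tricarboxylic acid cycle, IDH3A, a subunit of isocitrate dehydrogenase, fell 1.67-fold (edgeR adjusted p = 0.0277). The peroxisomal oxidase ACOX2 rose 1.64-fold among 25 genes of fatty acid oxidation, and the ferritin chain FTL 1.48-fold among 22 NRF2 targets. GPX1, a glutathione peroxidase, rose 2.03-fold among 22 glutathione and NADPH genes, the sulfotransferase SULT1A1 3.54-fold among 8 xenobiotic response genes, and the stress protein NUPR1 3.57-fold among 31 amino acid stress genes. PTTG1, the securin of mitosis, rose 1.29-fold among 31 mitosis genes, and AXL, a receptor kinase, fell 1.51-fold among 18 YAP targets. None of these 8 lists passed camera's test with all libraries. IDH3A, GPX1 and SULT1A1 also passed without R7 and R9, and the other 5 did not (edgeR adjusted p between 0.0703 and 0.103). Of these 5, NUPR1 was at 1.83 (log2) with all libraries and 1.88 without these 2, PTTG1 at 0.37 in both, FTL at 0.57 and 0.55, ACOX2 at 0.71 and 0.70 and AXL at -0.59 and -0.36, while IDH3A, which kept its call, moved from -0.74 to -0.46. With adjustment over each list alone, 2 rose and 4 fell in the tricarboxylic acid list (0 and 1 without R7 and R9), 2 and 1 in fatty acid oxidation (1 and 1), 2 and 1 among NRF2 targets (2 and 0), 3 and 3 in the glutathione list (3 and 1), 1 and 1 in xenobiotic response (3 and 0), 1 and 0 in amino acid stress (2 and 0), 1 and 0 in mitosis (0 and 0) and 1 and 5 among YAP targets (0 and 2). Over all genes, 0 members passed in edgeR of the lists for gluconeogenesis (5 tested), polyol and fructose use (5), steroid metabolism (11), hypoxia (23), DNA replication (29), p53 targets (20), inflammation (25), immediate early genes (31), WNT targets (13), NOTCH (12) and retinoid and vitamin D response (14). Of their 186 genes, 49 had an unadjusted p under 0.05, and DESeq2 called 28 and voom 0. When adjusted over each list alone, 1 fell in polyol and fructose use, 1 rose in steroid metabolism, 2 fell in hypoxia, 2 rose among p53 targets and 2 in inflammation, and 1 rose and 1 fell in the retinoid and vitamin D list, with none in the other 5. Without R7 and R9 these were 2 rising in steroid metabolism, 2 falling in DNA replication, and 1 rising each among p53 targets, inflammation and WNT targets. None of these 11 lists passed camera's test with all libraries.

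Markers of cell types were measured as a check of the culture. A test between the groups does not show what the cells are, so levels are given for some markers. Of 18 epithelial markers none passed over all genes in edgeR (5 had an unadjusted p under 0.05, DESeq2 called 4 and voom 0). The keratin KRT8 was at 2481 ± 236 CPM with DMSO and 1740.0 ± 338 CPM with progesterone (edgeR adjusted p = 0.0744). The epithelial markers MUC1, EPCAM and KRT18 were low, at 2.51, 1.42 and 4.055 CPM with DMSO. With progesterone they were at 1.05, 0.426 and 1.435 CPM. These epithelial markers were named for their small p and not for their level, so they may not represent all 18. Their levels were mixed and do not settle the identity of the cells. Of 21 stromal markers, POSTN fell and 20 did not pass. The fibrillar collagen COL1A2 was at 5295 ± 1412 CPM with DMSO and 3269 ± 257 CPM with progesterone (edgeR adjusted p = 0.0627), a log2 fold change of -0.70 and, without R7 and R9, of -0.31. Stromal markers deviated by 0.23 and 0.24 (log2, median) in R7 and R9 and by -0.19 to 0.07 in the other 6. Of 4 glandular markers measured AGR2 rose, and no member passed among 9 smooth muscle, 2 endothelial, 4 immune and 8 ciliated markers in edgeR (8 of these 23 had an unadjusted p under 0.05, DESeq2 called 5 and voom 0). These last 4 lists held 10 smooth muscle, 12 endothelial, 16 immune and 16 ciliated markers, and the filter removed the rest. Over each marker list alone, 2 epithelial markers fell, 1 stromal marker rose and 3 fell, and 1 smooth muscle marker rose and 2 fell. Over their lists 1 ciliated marker rose and 1 fell, 1 glandular marker rose, and 0 endothelial and 0 immune markers passed. Without R7 and R9 these were 1 stromal marker rising and 2 falling, 1 smooth muscle marker falling and 1 glandular marker rising. Of 12 replication histone genes, none passed in edgeR, over all genes or the list alone (3 had an unadjusted p under 0.05, DESeq2 called 2 and voom 0), and their median deviation was 0.46 and 0.68 in R7 and R9 and between -0.41 and 0.10 in the others.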

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

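A single library far from the other 3 of its group was looked for in 176 groups of 4 values, and 9 were found where chance gives about 8.80. DMSO R1 was the low library for LPIN1 (69.1 CPM, others 80.4 to 81.2), TKT (459.5 CPM, others 527 to 541) and SLC2A1 (62.6 CPM, others 114 to 118). Progesterone R3 was the high library for KRT6A (1.72 CPM, others 0.795 to 0.951), TALDO1 (372 CPM, others 305 to 316), SLC2A1 (135 CPM, others 58.4 to 69.3) and PIK3IP1 (43.3 CPM, others 36.3 to 37.2). IDI1 was low in DMSO R9 (101.5 CPM, others 125.5 to 129), and NUPR1 was high in progesterone R6 (4.51 CPM, others 1.90 to 2.11).

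The tests of depth, of swapped labels and of admixture were chosen after R7 and R9 had been seen to stand apart. The totals of both libraries lay inside the range of the other 6 (2 of 2 inside), which argues against sequencing depth. On 161 genes called without them, R7 and R9 sat at -0.208 and -0.253 on a scale from DMSO R1 and R3 (0) to progesterone (1), where the progesterone libraries lay between 0.932 and 1.03, which argues against labels swapped with progesterone libraries. Admixture of another cell type at a share under 75 percent cannot lower a transcript over 4-fold; 9 of 9265 genes over 10 CPM in each of the other 6 libraries were lowered that far in both (among them C3, WNT4 and GREB1, chosen after their values were seen), between the 5 and 20 set as bounds, so it stays open. Another culture, passage or day may also account for the pattern; the labels give none, and no biological explanation was tested.

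The tests named here were written before their results were seen. No split of the 8 libraries into 4 and 4 other than the real one called as many genes (1 of 35 splits, 359 genes, highest other 6) or as many core enzymes of the pentose phosphate pathway over their list (1 of 35, 2 enzymes, highest other 1). The 20 splits that part R7 and R9 called 0 of either, and the 15 that keep them together are too few for a share under 0.05. The count of core enzymes was also 0 without R7 and R9, DMSO R9, progesterone R1 or progesterone R3, and 1 without DMSO R3 or progesterone R2. For the 13 lists called by camera with the preset correlation chance is not excluded, since 5 of 35 splits called as many (highest other 15). At 95.7% of the genes called without R7 and R9 (154 of 161 measured in both fits, 95% exact binomial interval 91.2 to 98.2%), R7 and R9 lay on the DMSO side of the progesterone mean, against 57.3% of all genes tested. The same progesterone mean took part in choosing these genes, so other libraries tend to lie on the DMSO side even by chance. The 57.3% is therefore too low a baseline. The interval treats genes as independent and is too narrow for genes that vary together. The check thus cannot decide whether the level of the 2 remaining DMSO libraries set these calls.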

How the results depend on the processing

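Column numbers R1 and R3 occur in both groups, with nothing in the labels to say what they share. Deviations of same-numbered libraries correlated at 0.226 and 0.210. Pairs with unlike numbers correlated at -0.150 to 0.148, so the same-numbered pairs ranked highest. The planned test had no term for the number. A replicate block of column numbers compares only the 4 libraries numbered R1 or R3, with 1 residual degree of freedom. With this block 2531 genes passed (1450 higher, 1081 lower). A change of pseudocount was not run, since the table holds estimated counts. Leaving out R7 and R9, the term for them and the block were chosen after the data were seen. The count of 359 genes (229 higher, 130 lower) moved to 1830 with DESeq2 (888 and 942), to 27 at an adjusted p under 0.01 (23 and 4), to 162 without R7 and R9 (137 and 25) and, for genes lower, to 81 with the term and 78 with voom. The DESeq2 calls held all 359, and 122 of the 162 were among them. The remaining scalings, filters and settings gave 324 to 367 genes, and voom gave 277 and the term 278. The share of higher genes was 63.8%, and 54.0% with library size only, 71.4% without a filter, 71.8% with voom and 48.5% with DESeq2. No scaling moved the median of all genes by more than 0.009 (log2, upper-quartile). Leaving out each library gave 42 to 1782 genes, 36 to 818 higher and 6 to 964 lower. Those without DMSO R1 (1782) and R3 (795) leave R7 and R9 as most of the DMSO group; the cause of the low counts without other libraries was not tested. The count of 13 lists was 0 with an estimated correlation, 6 with fry (5 of the 13) and 16 with the block (9 of the 13), and leaving out each library gave 13 to 15. Core pentose phosphate enzymes called over all genes numbered 0, and 2 with DESeq2 and 4 with the block; leaving out each library gave 0 to 1, with 1 without DMSO R1 and 1 without DMSO R3. Adjusted over the list alone they numbered 2, and 4 with DESeq2 and with the block, 0 without R7 and R9 and 0 to 4 leaving out each library. Of 61 named genes called, none changed sign in the fits run for named genes. All 359 called genes were without overlap between the groups, so a sign could hardly turn and this is no evidence of stability. Of the 61, 60 kept the call with DESeq2's size factors, 58 with library size only, 61 with DESeq2 and 51 with voom. The call was kept by 35 without R7 and R9, 44 with the term, 57 with the block and 17 to 61 leaving out each library. Signs turned for some genes that did not pass. Without R7 and R9 and with the term, log2 fold changes were -0.067 and -0.081 for PGLS, 0.14 and 0.13 for SLC2A3, -0.011 and -0.025 for PAQR8 and -0.013 and -0.027 for ESR1, and PGRMC2 was at 0.0036 without R7 and R9. With the block they were -0.065 for PGLS, 0.15 for SLC2A3, 0.054 for SLC2A1, -0.059 for PAQR8 and -0.030 for PAQR6. PAQR6 was between -0.071 (without progesterone R6) and 0.12 (without progesterone R2), and at -0.013 without DMSO R3. The DNA replication list turned lower without R7 and R9 (camera adjusted p = 0.00566), with the term (0.00443), with the block (0.049) and without R7 or R9 alone (0.666 and 0.876), and the amino acid stress list without DMSO R1 (0.623). With an estimated correlation the first 3 were 0.649, 0.575 and 0.815, and no list passed in any of these fits. Leaving out each library gave camera adjusted p of 0.233 to 0.989 for the DNA replication list and 0.211 to 0.989 for the amino acid stress list. In simulated counts, which left out the distance of R7 and R9 from the other DMSO libraries, 2-fold changes were recovered in 76.0% of genes. A gene that did not pass is therefore not shown to be unchanged.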

Other observations

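Several genes were higher in R7 and R9 than in each of the other 6 libraries, chosen here after their values were seen. The neural crest and muscle transcription factor PAX3 was at 50.7 and 52.1 CPM in R7 and R9 and between 1.16 and 3.76 CPM in the others. The laminin chain LAMA4 was at 46.3 and 48.9 CPM against 0.307 to 1.74 CPM, and N-cadherin, CDH2, at 194 and 175 CPM against 11.6 to 25.0 CPM. Fibronectin, FN1, was at 13742 and 13064 CPM against 3636 to 4415 CPM. In all, 59 genes over 10 CPM in both were over 4-fold above the highest of the other 6 libraries. VIM, a mesenchymal filament, was between 5814 and 7467 CPM in the 8 libraries, and EPCAM, an epithelial adhesion molecule, at most 2.53 CPM.

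Ribosomal protein genes were higher with progesterone, with 71 of 71 having a positive log2 fold change and a median of 0.388; the test of R7 and R9 was chosen after the result was seen, and that of matched lists before. For comparison, 10000 lists were matched on gene length (span in the reference table, introns included) and mean expression. Their medians had a middle of 0.105, and the upper end of their central 95% was 0.192. The middle argues against gene span and expression as the whole cause. Transcript length was not matched. Members were drawn singly, so the range is too narrow for genes that vary together (estimated correlation 0.593 for the ribosomal list). Without the 2 DMSO libraries that stand apart the median was 0.328, which argues against them as the whole cause, while the members past the threshold over the list alone went from 65 to 0 in that smaller comparison. Progesterone R1 (-0.05) lay beside DMSO R3 (-0.06), and the adjusted p was 0.630 with an estimated correlation, so a technical difference between single libraries may still account for the pattern.

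Clock genes moved in opposite directions. CRY1 fell and PER1 rose, and PER2 and CIART, chosen after their values were seen, were 2.89-fold and 2.83-fold lower (edgeR adjusted p = 0.0106 for both, and 0.00855 and 0.0220 without R7 and R9). A shift of clock phase between the groups was a candidate explanation, with its test written before the other clock genes were seen. Of 9 other E-box clock genes (PER3, CRY2, NR1D1, NR1D2, DBP, TEF, HLF, BHLHE40 and BHLHE41) 0 passed in edgeR, DESeq2 or voom (2 had an unadjusted p under 0.05 in edgeR), with a median log2 fold change of -0.160; without R7 and R9 the median was -0.214 and 5 of 9 were lower. Of the activators ARNTL and NPAS2 0 passed as well. The test had left out the 4 clock genes already seen to change, so it excludes nothing and a shift of phase stays open; a direct response of single genes to the hormone was not tested.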
